A study of Mus musculus with 2 samples.

How the data were processed

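CLIP-seq libraries of Flag-tagged DDX10 were made from mouse E14 embryonic stem cells, in 1 group of 2 replicates, per the labels. The labels' protocols describe ultraviolet crosslinking, nuclear extracts, DNase treatment, purification on Flag beads, partial digestion by micrococcal nuclease, linker ligation, gel separation, reverse transcription and PCR. No molecular identifiers are described, so reads copied by PCR may be counted more than once.

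The deposited files were 1 annotated peak list per replicate, so peaks were called per library and not on pooled reads. Reads were aligned to the mm10 build, and BWA, ChIPseeker and deepTools were named, per the submitters' processing notes, which give no version or role for them here. The peak caller, its read filters and any use of a control library are not given in the sources used here. The authors' signal value of a peak was its height in tags, which equalled the PH field of the peak's name in every line and was taken here as the greatest number of overlapping tags. Heights are whole numbers of tags with no scaling for depth. Other columns deposited by the authors gave the width in bp, the distance to a transcription start and, in the peak's name, a gene ID, an expected height (PH0) and a p-value. Each peak also had an annotation class and a nearest gene from the authors' annotation, which calls a peak promoter within 1 kb of a transcription start, judging from the largest distance of 988 bp. The largest p-value that the authors' peak caller gave was 0.0471 in replicate 1 and 0.0396 in replicate 2. Because nuclease trimming shortens tags and peaks were at most 45 bp wide, the same binding site may be split or missed in either list.

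The lists held 133 and 98 peaks. In each, 2 positions were listed under 2 gene IDs, and they were counted a single time, which left 131 and 96 distinct peaks. Of the gene IDs a position carried, the ID near the peak was kept. The total number of reads per library is unknown, and the heights of all peaks added up to 3491 and 2687 tags. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals.

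Gene coordinates and names came from a RefSeq table of 49997 genes on the GRCm38.p6 assembly, the same build as mm10. Of 155 annotated gene IDs, 154 were found in it, and the exception, Rn45s, was added to make a background of 49998 genes. The table gives neither strand nor exons. No genome sequence was used, so peaks were not matched to the 45S pre-rRNA sequence, and annotation classes were not compared with random positions.

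Tests were fixed before the data were examined. Peaks were shared where they overlapped by at least 1 bp, and the count was set against 10000 random placements of the replicate 2 peaks on gene bodies, with the same widths. Genes in both lists were tested with Fisher's exact test, one-sided. Annotation classes were compared between replicates with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over classes. Heights at shared peaks were compared by Spearman's rho and Pearson's r on the log scale with 100000 permutations, adjusted over the 6 correlations computed. The 15 gene lists covered ribosomal RNA, genes holding rRNA-like repeats, snoRNA and scaRNA genes, snoRNA host genes, spliceosomal and other small structured RNAs, nuclear long noncoding RNAs, tRNA and microRNA genes, ribosomal proteins, ribosome biogenesis factors, pluripotency genes, histone genes, mitochondrially encoded genes, abundant housekeeping transcripts, satellite-like predicted genes and markers of other cell types. Each list was tested with Fisher's exact test, two-sided, over the genes with a peak in either replicate, with Benjamini-Hochberg adjustment over the 15 lists and a threshold of 0.05. The lists were written from general knowledge, and their members' sequences were not checked. The test and counts of the list of genes holding rRNA-like repeats rest in part on an item that is not reported here, so only values of its other genes and of its shared peaks, which leave that item out, are given.

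Genes and regions were named by a rule fixed before the data were examined: up to 5 peaks per gene list by mean rank of height with shared peaks first, the 10 shared peaks with the best mean rank, the 5 best-ranked peaks of each list that had no partner, and every gene with at least 3 peaks in a list. Names outside this rule are said to be so where they appear, or complete a count of members. Overlap of peaks with RefSeq snoRNA genes was added after the data were seen. The share of peaks in gene bodies stands for the part of the fixed comparison with random positions that gene coordinates alone allow.

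Alternatives covered the overlap that counts as shared, peaks at or above the median height of each list, leaving out ribosomal RNA, merging peaks within 1 kb, placement on whole chromosomes, shares of covered bases, 1 peak per gene and class, shared peaks only, leaving out distal intergenic peaks, protein-coding genes as background, and each replicate left out. Alternatives added after the data were seen were listed repeats, summed heights, the gene ID that the peak caller wrote, leaving out peaks whose caller gene ID lies over 100 kb away, snoRNA genes by symbol, and snoRNA genes only where they hold the peak named after them. The overlap and gene list tests were tested on simulated data, in 40 simulations with a planted effect and 40 without. All 20 peaks planted as shared were recovered in each, for lists of 131 and 96 peaks. They were planted at their exact replicate 1 positions, so their recovery was certain. The other simulated peaks were drawn uniformly from gene bodies, with fewer placements per test, so uneven expression was not simulated. With 5 planted snoRNA genes among 155, the snoRNA list passed in all 40. Without a planted effect, the overlap passed in 0 of 40 simulations, and any of the 15 gene lists passed in 1 of 40. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.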

Results

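RNA bound by the RNA helicase DDX10 was measured by CLIP-seq in mouse E14 cells, an embryonic stem cell line that stably expressed DDX10 with a Flag tag. In CLIP-seq, ultraviolet light crosslinks protein to RNA, the tagged protein is purified with its RNA fragments, and the fragments are sequenced and mapped to the genome. Here the purification was made from nuclear extracts, and the RNA was trimmed by partial nuclease digestion. The series had 1 group of 2 libraries, called replicate 1 and replicate 2. The labels do not say that the replicates came from separate cultures, so the spread between them may be technical. Each library came with its own list of peaks. Replicate 1 held 131 distinct peaks in 110 annotated genes, covering 2500 bp, and replicate 2 held 96 distinct peaks in 84 annotated genes, covering 1794 bp. Peaks were short, with a median width of 20 bp in replicate 1 and 18 bp in replicate 2. Peak heights, which are the authors' values in tags, ran from 3 to 578 in replicate 1 and from 3 to 604 in replicate 2, with a median of 5 in both. A height of 3 was the lowest in either list, and 27.5% of peaks in replicate 1 and 28.1% in replicate 2 stood at it. The number of reads per library is unknown and heights were not scaled for it. Control or input libraries were not analysed here, so heights are not set against the abundance of each RNA.

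The series title names 18S rRNA processing as its subject, and the first question was how much of the DDX10 signal lay on ribosomal RNA. The highest peaks of both lists were at Rn45s, the gene symbol of the precursor of 18S, 5.8S and 28S rRNA. They were few, with 8 of 131 peaks in replicate 1 and 9 of 96 in replicate 2, and they made up most of the summed peak height. Their heights added up to 2233 of 3491 tags in replicate 1 (64.0%) and 2000 of 2687 tags in replicate 2 (74.4%), a mean of 69.2% ± 7.40 (SD, n = 2). The 5 highest peaks of replicate 1 and the 9 highest of replicate 2 were at Rn45s. As a share of peaks, Rn45s held 6.11% in replicate 1 (95% exact binomial interval 2.67% to 11.7%) and 9.38% in replicate 2 (4.38% to 17.1%), a mean of 7.74% ± 2.31 (SD, n = 2). These and the other intervals cover counting error only, since reads copied by PCR are not independent molecules. The Rn45s peaks covered 28 bp in replicate 1 and 27 bp in replicate 2, or 1.12% and 1.51% of the bases in peaks. Their mean height was 279 tags in replicate 1 against 10.2 tags at all other peaks, and 222 tags against 7.90 tags in replicate 2.

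All Rn45s peaks lay on the plus strand of chromosome 17 in the mm10 build. RefSeq places a copy of 18S sequence there, Rn18s-rs5, a pseudogene of 1849 bp from 39846354 to 39848202. Inside this copy lay 7 of the 8 Rn45s peaks of replicate 1 and all 9 of replicate 2. The annotated Rn45s transcript spans only 1831 bp here, from 39846958 to 39848788, and overlaps the copy. Peaks named Rn45s thus had little room outside the copy. Their location does not show a preference for 18S over other parts of the precursor. Bases of the copy are counted here from its lowest coordinate, since its strand is not given, and were not aligned to 18S rRNA. The highest peak in both lists was at 39847210, base 857 of the copy, with a height of 578 in replicate 1 and 604 in replicate 2, where it spanned 39847208 to 39847210. The other peaks found in both lists lay at 39847782 (base 1429; heights 338 and 294), at 39846489 to 39846492 (from base 136; 279 and 240), at 39846902 to 39846904 (from base 549; 264 and 245) and at 39846760 to 39846764 (from base 407; 155 and 96). Across these 5 shared peaks the height in replicate 2 was 0.619 to 1.04 times that in replicate 1. Replicate 1 alone held peaks at 39846608 to 39846613 (height 363), at 39847052 to 39847057 (height 183) and, 304 bp past the end of the copy, at 39848506 to 39848507 (height 73). Replicate 2 alone held peaks at 39846678 to 39846679 (height 182), 39847582 to 39847583 (height 209), 39848058 to 39848060 (height 72) and 39848123 to 39848134 (height 58). The expected height that the peak caller wrote for this gene was 26.8 tags in replicate 1 and 16.8 tags in replicate 2. Observed heights were 2.72 to 21.6 times it in replicate 1 and 3.46 to 36.1 times it in replicate 2. Since copies of rRNA genes are nearly identical, this position stands for all copies whose reads were placed there.

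**Figure D1:**
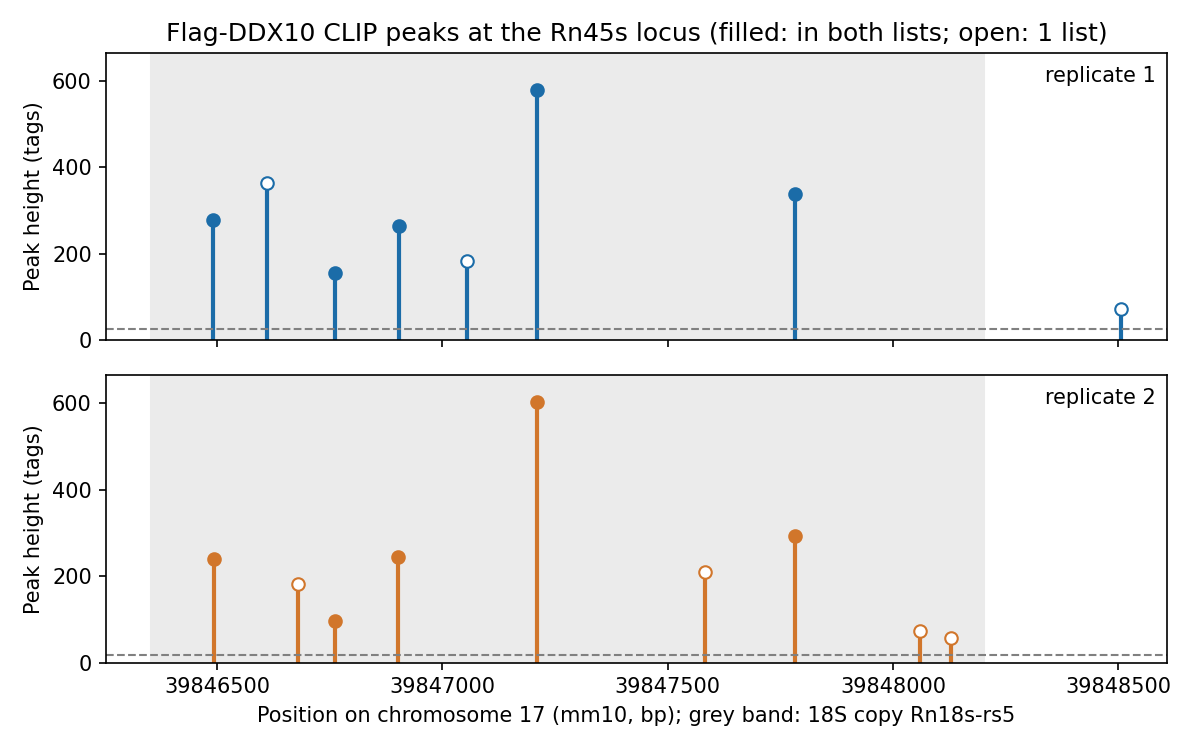
Peak height in tags (vertical axis) against position on chromosome 17 in bp (horizontal axis) for the Rn45s peaks of replicate 1 (top) and replicate 2 (bottom). Filled points are the 5 peaks found in both lists, open points those of 1 list, the grey band is the 18S copy Rn18s-rs5, and the dashed line is the height expected by the peak caller. The highest point stands near 39847210 in both libraries, at 578 and 604 tags.

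Genes known to hold rRNA-like sequence in their bodies, where rRNA reads can be placed, formed the next group. Cdk8, the kinase of the Mediator complex, Filip1l, and Lars2, the mitochondrial leucyl-tRNA synthetase, each had peaks in both replicates. In intron 1 of 4 of Filip1l, on chromosome 16, a peak at 57391520 had a height of 192 in replicate 1 and 30 in replicate 2, and another at 57391645 to 57391648 had heights of 71 and 33. The peak caller gave both to Cmss1, a further member of the list. Both lay on the minus strand, antisense to Filip1l, judging from distances to its start that rise with the coordinate. In intron 2 of 11 of Cdk8, on chromosome 5, the peak at 146261279 to 146261283 had heights of 96 and 19, and replicate 1 alone had peaks of height 42 at 146261083 to 146261086 and 12 at 146261194 to 146261207, and replicate 2 alone a peak of height 17 at 146261023 to 146261028. In the 3' UTR of Lars2, on chromosome 9, the peak at 123461987 to 123461989 had heights of 42 and 28, and replicate 1 alone had peaks of height 6 and 7 nearby. On chromosome 2 at 5379310 to 5379335, an intronic peak with Ccdc3 as the gene in the authors' annotation, given by the peak caller to Camk1d, also of the list, had heights of 43 and 22. By the same reading of distances, this minus-strand peak was antisense to Ccdc3. The sequences of these peaks were not compared with rRNA.

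Small nucleolar RNAs (snoRNAs), which guide modification and cleavage of rRNA, had peaks in both replicates, most of them in replicate 1. By the authors' gene symbols, 7 of 150 snoRNA and scaRNA genes were named for a peak: Snord22, Snord65, Snord96a, Snord14c, Snora3, Snora41 and Scarna9. The list went by symbol, whereas RefSeq types 1381 genes as snoRNA or guide RNA, so the test below covers the list alone. A random draw of genes would give 0.465 (Fisher's exact test, two-sided, adjusted p = 3.66e-06), but 6 of the 7 came from replicate 1 alone, and without replicate 1 the adjusted p of the same exact test was 0.670. Of the 7 genes, 4 held the peak named after them, namely Snord22, Snord65, Snord14c and Snora41, and with these 4 alone the adjusted p of the exact test, chosen after the data were seen, was 0.00590. Peaks at these genes numbered 7 in replicate 1 and 1 in replicate 2, a difference that did not pass Fisher's exact test (p = 0.143, adjusted p = 1). Snord22, a box C/D snoRNA needed for 18S processing and encoded in an intron of Snhg1, had the highest snoRNA peak, on chromosome 19 at 8725906 to 8725909, with a height of 85 in replicate 1 and 17 in replicate 2. Snord14c, a copy of the U14 snoRNA that pairs with 18S rRNA, had a peak of height 8 in replicate 1 alone, on chromosome 9 at 40803615 to 40803633. The list of genes that carry snoRNAs in their introns, which does not hold all such genes, had 3 of 62 members with a peak. A random draw would give 0.192 (Fisher's exact test, adjusted p = 0.00483), and without replicate 1 the adjusted p of this exact test became 0.456. They were Eif4g2, a translation initiation factor, with heights of 22 and 7 on chromosome 7 at 111076186 to 111076208, and, in replicate 1 alone, Eif4a1, an RNA helicase of translation initiation, and the chaperone gene Hspa8, each with a height of 7.

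Counted by position, an approach chosen after the data were seen, peaks overlapped a RefSeq snoRNA or guide RNA gene 11 times in replicate 1 (8.40%, 95% exact binomial interval 4.27% to 14.5%) and 2 times in replicate 2 (2.08%, 0.253% to 7.32%). Random placement on gene bodies gave means of 0.02 and 0.0151 such peaks (one-sided permutation p = 0.0001, the smallest that 10000 placements can give, and p = 0.0004). The placements left out the abundance of each RNA, so the excess is not shown to come from DDX10 binding. The peaks at Eif4g2, Eif4a1 and Hspa8 were among the 11, since each overlapped a snoRNA gene inside its host. At Hspa8 this was Snord14e, another U14 copy. The test of the host list is thus not separate from the snoRNA signal. Of the 11, the others that the gene symbols had not given were at Epb41l4aos (height 14), Ddx39b (height 5) and Cnot1 (height 5). The peaks named after Snord96a and Scarna9 lay beside those snoRNA genes and not in them, and the peak named after Snora3 lay in another RefSeq snoRNA gene, LOC115485611. Between the replicates, 11 of 131 peaks against 2 of 96 gave Fisher's exact p = 0.0474 (two-sided, not adjusted). The 13 and 2 peaks at snoRNA genes by symbol or position held 5.44% of summed heights in replicate 1 and 0.893% in replicate 2.

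The other gene lists reported here did not pass Fisher's exact test (two-sided, adjusted over the 15 lists). Among 77 ribosome biogenesis factors, Rrp12, a pre-ribosome export factor, had a peak of height 4 in both replicates, with identical bounds in intron 8 of 33 on chromosome 19 at 41886527 to 41886545 (exact test, adjusted p = 0.532). As a list of genes rather than of peaks, ribosomal RNA had 1 of 75 members with a peak, Rn45s (exact test, adjusted p = 0.532). That count goes by gene symbol and leaves out a peak in both replicates at Tmem38b, which overlapped a RefSeq rRNA gene, LOC115490001. Of 20 abundant housekeeping genes, Hspa8 had a peak (exact test, adjusted p = 0.226), and of 109 histone genes, H2al1n was named for a peak of height 3 that lay 104328 bp from its transcription start (adjusted p = 0.616). The microRNA genes Mir592, Mir6237, Mir6406 and Mir7044 were named as the nearest genes of peaks that lay from 5658 to 562182 bp away, 4 of 1582 tRNA and microRNA genes against 4.90 for a random draw (exact test, adjusted p = 1). Pluripotency genes, 33 in number and including Pou5f1, Sox2 and Nanog, had 0 peaks. The lists of ribosomal proteins (85 genes), spliceosomal and other small structured RNAs (25) and nuclear long noncoding RNAs such as Malat1 and Neat1 (10) also had 0 peaks. So did the lists of markers of other cell types of such cultures (23) and of mitochondrially encoded genes. The mitochondrial list held only the 2 genes that matched by symbol, not the whole class. For each of these lists and the pluripotency genes, a random draw would give at most 0.264 genes, so a count of 0 cannot show a lack of binding. The counts of 0 go by gene symbol too: peaks at Col4a3, Zfp791, Stac, Pag1, Kdm6a and Fam133b, named after their values were seen, and the H2al1n peak counted above lay in transcripts with no gene ID, whose kind of RNA was not determined, so small RNA genes there would not be counted. The mitochondrial chromosome had 0 peaks, and satellite-like predicted genes had 0 peaks and 0 members among the genes tested. Spata5, an AAA-type ATPase gene outside the lists, was the other gene with 3 peaks in a library: in replicate 1 they stood in intron 14 of 15 on chromosome 3 between 37481372 and 37481662, with heights of 18, 17 and 5, and the peaks of height 18 and 17 each had a partner of height 3 in replicate 2. These tests gave each gene the same chance of a peak whatever its length or expression.

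Peaks found in both replicates addressed how far the libraries marked the same places. They included 5 peaks at Rn45s, those at Filip1l, Cdk8, Lars2, Ccdc3, Snord22 and Eif4g2, and 25 intronic peaks in all. In total 44 peaks overlapped by at least 1 bp, or 33.6% of replicate 1 (95% exact binomial interval 25.6% to 42.4%) and 45.8% of replicate 2 (35.6% to 56.3%). Placing the peaks of replicate 2 at random on gene bodies gave a mean of 0.0003 shared peaks and a maximum of 1 (one-sided permutation test, p = 0.0001, the smallest that 10000 placements can give). The placements left out how much RNA each gene gives, so libraries of the same cells could exceed them for that reason alone. All 44 pairs lay on the same strand and in the same annotation class, and 16 had identical start and end. Of peaks with a height of 10 or more, 21 of 32 in replicate 1 and 20 of 30 in replicate 2 were shared, against 6 of 36 and 9 of 27 at a height of 3. The peaks with no partner numbered 87 in replicate 1 and 52 in replicate 2. Outside Rn45s, these included the Cdk8 peak of height 42 in replicate 1 and, in replicate 2, a peak of height 22 on chromosome 11 at 98004262 to 98004279, annotated to Arl5c and given to Cacnb1 by the peak caller. At this number of tags, a peak missing from a list is not shown to be absent from the library.

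Heights at the 44 shared peaks were correlated between replicates, led by Rn45s and followed by Filip1l, Cdk8 and Lars2. On the log scale, Spearman's rho was 0.669 (permutation p = 1e-05, adjusted p = 2e-05) and Pearson's r was 0.827 (permutation p = 1e-05, adjusted p = 2e-05), where 1e-05 is the smallest that 100000 permutations can give. This correlation runs across peaks, which are not independent replicates. Without the Rn45s peaks, 39 pairs gave rho of 0.523 (permutation p = 0.0007) and r of 0.575 (permutation p = 0.00016). The height was greater in replicate 1 at 25 peaks, greater in replicate 2 at 14 and equal at 5, with a median ratio of replicate 2 to replicate 1 of 0.805 among peaks that reached 3 tags in both. At the 5 shared peaks of genes with rRNA-like repeats, counting Camk1d, all 5 were higher in replicate 1, with a median ratio of 0.465, whereas the 5 Rn45s peaks had a median ratio of 0.870. Peaks that stood higher in replicate 2 included those at Col4a3 (heights 11 and 38), Ica1 (7 and 28) and Zfp791 (5 and 20), named after their values were seen.

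**Figure D2:**
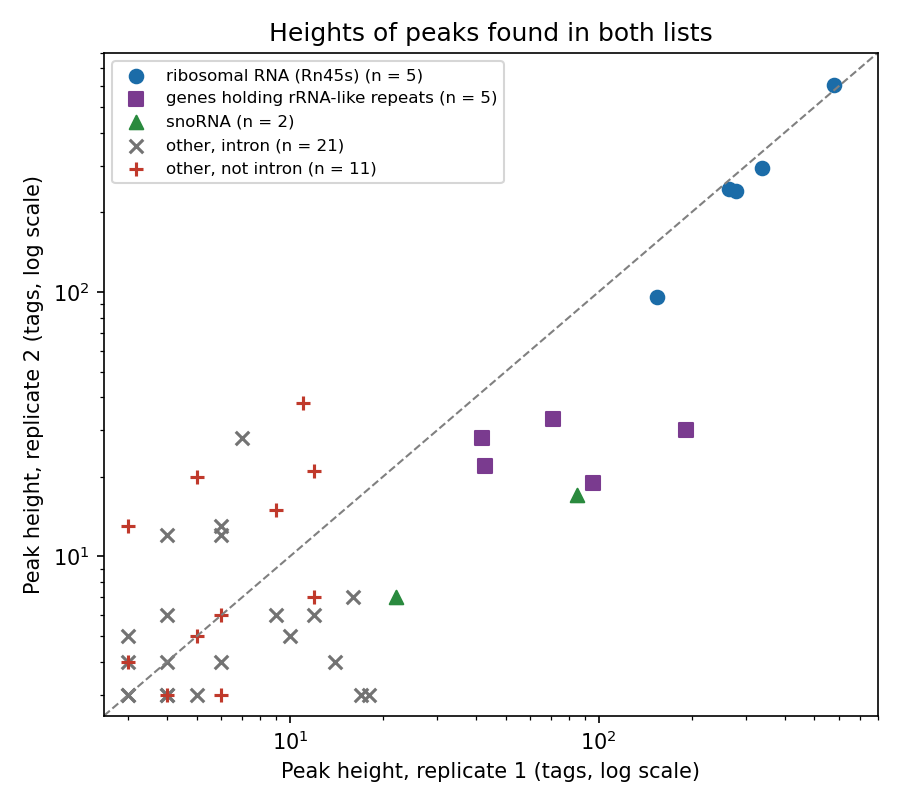
Height in replicate 2 against height in replicate 1, both in tags on log axes, for the 44 peaks found in both lists; each point is a peak, its symbol gives the group, and the dashed line marks equal heights. The Rn45s peaks stand at the upper right near the line, and the peaks of genes with rRNA-like repeats and of snoRNAs all lie below it.

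The same genes were marked more often than independent lists would give. In both replicates 39 annotated genes had a peak, among them Rn45s, Cdk8, Filip1l, Lars2, Snord22, Eif4g2, Spata5 and Rrp12. These were 35.5% of the 110 genes of replicate 1 and 46.4% of the 84 genes of replicate 2. Independent lists drawn from 49998 genes would share 0.185 genes (Fisher's exact test, one-sided, p = 1.33e-83). Genes differ in length and expression, which this background leaves out. The gene that the authors' annotation named and the gene that the peak caller had written differed at 42 of the 227 distinct peaks, as at Filip1l and Ccdc3.

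Introns held most peaks in both replicates. Of the peaks, 81 (61.8%) in replicate 1 and 56 (58.3%) in replicate 2 were intronic, a mean of 60.1% ± 2.47 (SD, n = 2), and they were low, with a median height of 4 in both. The promoter class came next, with 28 (21.4%) and 20 (20.8%) peaks, a mean of 21.1% ± 0.382 (SD, n = 2). It held 7 of the Rn45s peaks in each replicate, since these lay within 1 kb of the start of the annotated Rn45s transcript at 39846958, and 9 and 2 peaks in snoRNA genes; 12 and 11 promoter peaks were at neither. Exons held 11 (8.40%) and 13 (13.5%) peaks, 3' UTRs 7 (5.34%) and 6 (6.25%), and distal intergenic positions 4 (3.05%) and 1 (1.04%). No class share differed between the replicates by Fisher's exact test (two-sided, lowest unadjusted p = 0.275, all adjusted p of at least 0.975). By RefSeq, 126 of 131 peaks (96.2%) and 95 of 96 peaks (99.0%) lay in a gene body, against 45.9% and 46.0% of the same peaks placed at random on chromosomes (one-sided permutation p = 0.001 in both, the smallest that 1000 placements can give). The peak caller wrote a gene for each peak, so this share may have been set by where it searched.

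**Figure D3:**
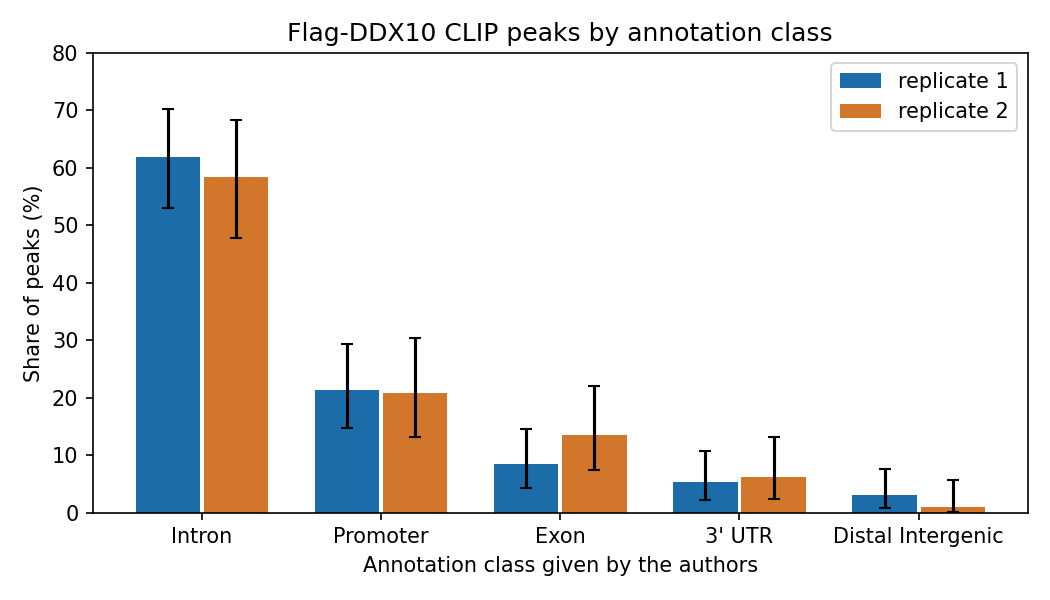
Share of peaks in percent (vertical axis) in each annotation class given by the authors (horizontal axis), for replicate 1 with 131 peaks and replicate 2 with 96 peaks; error bars are 95% exact binomial intervals. Introns hold 61.8% and 58.3% of peaks, and the intervals of the replicates overlap in every class.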

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

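Over all results, 127 alternative values were labelled unchanged. Most of them kept their direction and their side of the threshold or moved by less than the spread between replicates. Another 18 moved, by more than that spread where a spread was available. Counts of shared peaks, shared genes and snoRNA peaks had no such spread. A further 5 lost a call, and 11 crossed the expected count of a gene list that had passed no test. The 127 include the alternatives of gene lists that had 0 peaks throughout, which could hardly change. The alternatives using summed heights, the peak caller's gene ID, distant gene IDs, listed repeats, snoRNA symbols and snoRNA genes that hold their peak were chosen after seeing the data. The p-values of the overlap of peaks and of genes passed under every alternative run; among peaks at or above the median height of each list 26 peaks and 22 genes were shared, fewer because fewer peaks enter. The Rn45s share was 1.31% of covered bases and 69.2% of summed heights, since its peaks are narrow and high. Introns held 46.8% of these higher peaks, 64.4% of covered bases and 56.8% of shared peaks. The promoter class held 28.8%, 16.4% and 22.7% of the same, and 18.1% at 1 peak per gene and class. Exons held 15.1% of the higher peaks, and 3' UTRs 6.99% of them, 7.74% of covered bases and 9.09% of shared peaks; distal intergenic positions held 0 shared peaks. The cause of these class shifts was not tested. The snoRNA list lost its call among shared peaks only (Fisher's exact test, adjusted p = 0.316) and by the peak caller's gene ID (0.674), which names the host gene, and ranged from 3.50e-07 to 0.670 when a replicate was left out, the higher value without replicate 1. The snoRNA host list had an adjusted p of 0.208 among shared peaks only and ranged from 0.00178 to 0.456, again the higher without replicate 1; by the peak caller's gene ID it held 5 genes with a peak (exact test, adjusted p = 9.00e-06). Among lists that passed no test, tRNA and microRNA genes had 0.819 among shared peaks only and 0.856 to 1 with a replicate left out, ribosomal proteins 0.478 by the peak caller's gene ID, and biogenesis factors 1 among the higher peaks. Histone genes had an adjusted p of 1 among the higher peaks, among shared peaks only, by the peak caller's gene ID and without distant gene IDs, and 0.458 to 1 with a replicate left out; housekeeping genes had 1 among shared peaks only and 0.162 to 1 with a replicate left out. The alternatives not run were the match to the 45S sequence, and classes against random positions on the genome or gene bodies. No paired analysis was possible because the series has 1 group. With 27.5% and 28.1% of peaks at the lowest height of 3 tags, depth limits what either list can show.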

Other observations

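All tests in this part were chosen only after the result was seen, except the test of gene length, and the peaks named here were chosen after their values were seen. No biological explanation was tested, since both libraries belong to 1 group.

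Other peaks lay at genes outside the fixed lists. On chromosome 9, Mrpl3, a mitochondrial ribosomal protein gene, had a promoter-class peak at 105064801 to 105064816 with heights of 12 in replicate 1 and 21 in replicate 2. The Col4a3 peak on chromosome 1 at 82635077 to 82635094 and the Zfp791 peak on chromosome 8 at 85112031 to 85112036 each lay in the exon of a single-exon transcript that the authors' annotation gives no gene ID. An exonic peak at N4bp2 on chromosome 5, at 65803502 to 65803517, had identical bounds in both replicates and heights of 9 and 15. In the 3' UTR of Tmem38b on chromosome 4, a peak from 53860700 (heights 6 and 3) overlapped a gene that RefSeq types as ribosomal RNA. In replicate 1, Ica1 and Col6a6 each had 2 intronic peaks on the minus strand with starts 146 bp apart, and heights of 6 and 7 at both genes. In replicate 2 this match did not recur: the Ica1 starts lay 151 bp apart, with heights of 4 and 28, and Col6a6 had only a peak of height 12.

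Introns held 25 of the 44 shared peaks, with a median height of 6 in replicate 1. Uniform chance placement of tags over gene bodies is argued against, since 25 intronic peaks were shared where the highest of 10000 such placements gave 1. These placements left out expression, so chance overlap on expressed RNA stays open. Short tags with ends set by a sequence held elsewhere in the genome stay open: 40% of shared intronic peaks (10 of 25) had identical bounds against 31.6% of the other shared peaks (6 of 19; one-sided Fisher's exact p = 0.400), too few to decide. A placement in proportion to gene length could account for the median length of the genes that hold intronic peaks. That median, 148 kb, lay inside the range of 82.5 to 163 kb (95% of 10000 random placements, median 116 kb). The test used lengths alone, so it does not say which genes hold peaks. Such placement does not account for the 25 shared intronic peaks, as stated above. Long genes also give more unspliced RNA in nuclear extracts, which was not tested.

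SnoRNA peaks were fewer in replicate 2, with 2 against 11 by position. A lower depth of replicate 2 overall stays open, since the median height ratio of replicate 2 to replicate 1 depends on which shared peaks outside snoRNA genes are taken, against 0.318 at the higher of the 2 shared snoRNA peaks. Over all 42 it was 0.865 (bootstrap 95% interval 0.667 to 1). If replicate 2 were shallower, that value would be biased upward, because a shared peak has at least 3 tags in both lists. Over the 14 outside Rn45s with a height of at least 10 in replicate 1 it was 0.482 (0.231 to 0.583). This second value is biased downward because peaks were picked for their height in replicate 1. With the 5 Rn45s peaks added it was 0.512 (0.438 to 0.860). SnoRNA tags of replicate 2 under the minimum peak height may account for the missing peaks: at the pooled ratio of the shared snoRNA peaks (0.224), 10 of the 11 snoRNA peaks of replicate 1 alone would fall under 3 tags. That ratio rests on the peaks at Snord22 and Eif4g2 alone. It takes the drop at snoRNA peaks as given, so it cannot say why snoRNA heights were lower in replicate 2. The 11 peaks include those named after Snord96a and Scarna9.

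The 5 distal intergenic peaks had heights of 3 to 9 and no partner in the other replicate. Gene IDs whose copies were joined into 1 long search span by the peak caller could account for them, which stays open. For 5 of the 5 the gene ID it wrote lay over 100 kb away or on another chromosome in RefSeq, against 4 of the other 222 peaks, but all 5 lay outside RefSeq gene bodies, so that a distant ID is largely built into the class. The 9 peaks with such an ID carried 3 IDs and are not independent, with 4 peaks under Snora19 spread over 10.6 Mb of chromosome 19, 4 under Btbd35f15 spread over 6.47 Mb of chromosome X and 1 under Mir297c. Of these, Snora19 counts as a snoRNA gene only where genes are taken from the peak caller's gene ID.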
